A study of Homo sapiens with 4 samples.

How the data were processed

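RNA was measured by sequencing in 2 established human liver cancer cell lines, Huh7 and HepG2. Per the labels' protocols, the cells were grown in DMEM with 10% fetal calf serum and seeded either on uncoated plates or on plates coated with rat tail collagen 1 at 5 ug/cm2, which had been dissolved in 0.02 M acetic acid and dried in air. Per the labels, the cells stayed on the plates for 2 days, total RNA was isolated with Trizol, and libraries were made by a standard Illumina procedure. There was 1 library for each combination of line and plate, 4 in all, and each library was placed in its group by its title. Nothing in the labels says whether the plates were prepared, seeded or sequenced together, or whether the kit kept strand.

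The authors deposited 1 table of RSEM expected counts per library, in which each value estimates the number of reads or fragments from 1 gene and need not be whole. Per the submitters' processing notes, STAR 2.7.2b, RSEM 1.3.1 and the GRCh37 build were used; the gene annotation, the read length and any filter on reads are not given in the sources used here. RSEM shares reads that match several genes among those genes in proportion to its own abundance estimates. A change in how reads were shared can therefore move a gene with near-identical copies, a readthrough gene or an overlapping gene. Genes recognised as such are reported as uncertain, and a gene without this mark may still share reads. The deposited expected counts were rounded to whole numbers, because the tests used need counts. No normalization had been applied to them, and every line of the tables named a gene.

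The tables held 57773 Ensembl gene identifiers with no names. Names were found for 52338 of them, 39538 in a table of current gene symbols and 12800 more in GENCODE 29, and the genes without a name held 0.754% of all counts. The annotation at hand belongs to another genome build than the files, so it was used for names, biotypes, which genes overlap, and transcript GC content and length, and no coordinates are given. A count above 0 in at least 1 library was found for 26020 genes.

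Total counts were 32349825 for uncoated Huh7, 20419484 for collagen Huh7, 19957079 for uncoated HepG2 and 21038359 for collagen HepG2. Over these totals, 1 CPM (the usual count scaled by library size) stood for 20.0 to 32.4 counts. A count of 0 allowed a level of up to 3 counts, which is 0.0927 to 0.150 CPM over the totals, and folds against a group at 0 counts are given as lower bounds against 3 counts over that group. All other CPM values and folds, these bounds included, are over TMM-scaled library sizes. Intervals and floors cover counting error only, since each group held 1 library. The reads also carry no molecular identifiers. In a chi-square comparison of raw counts, every pair of libraries differed by more than sampling noise, from 40.2 per degree of freedom for the HepG2 pair and 55.8 for the Huh7 pair to 196 for uncoated Huh7 against collagen HepG2, so no library appeared to have been deposited more than once.

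Within a line, the libraries on the coated and the uncoated plate were compared by size alone. The log2 fold was taken from CPM over library sizes scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 with a prior count of 2, and the 95% interval came from the exact conditional binomial (Clopper-Pearson) distribution of the 2 counts. A gene was measured in a line at 1 CPM or more in 1 of its libraries. It was counted as different at 2-fold or more with an interval that excluded no change, and these counts were set beside 100 simulated pairs of libraries that differed by Poisson counting alone. Such a comparison is between libraries, not conditions, and it has no replicate check and no p-value.

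Over both lines, each contrast was tested with the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, with the coating contrast blocked by line and the line contrast blocked by coating, over the 15209 genes kept by the expression filter of edgeR. A gene passed at an adjusted p below 0.05. In the coating test the lines were the only repeats, which left 1 residual degree of freedom; the spread was otherwise borrowed across genes, with 22.7 prior degrees of freedom and a biological coefficient of variation of 0.138. Nothing says that the libraries are independent cultures beyond the difference of line, so the p-values measure the spread between these 4 libraries only. The standard error (SE) of a log2 fold was its size divided by the square root of the quasi-likelihood F. The difference between the responses of the lines leaves no residual degrees of freedom and was not tested.

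Agreement of the coating folds between the lines was described by Pearson's r and Spearman's rho across genes with at least 5 CPM in 1 or more libraries of each line, with bootstrap intervals over genes, and by the overlap of genes at least 1.5-fold different in the same direction beside the overlap of independent lists. Genes are not independent replicates, so no p is given for these. A total of 36 gene lists with 726 entries, of which 715 were matched, covered matrix and adhesion, hepatocyte functions, lipid and sugar metabolism, cell cycle, stress and signalling, and markers of fibroblasts, endothelial cells and leukocytes. For each list the median log2 fold within a line was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries, and members past the test were counted over all genes and adjusted over the list alone.

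Named genes followed a rule. For each line these were the 10 highest and 10 lowest folds among genes with at least 5 CPM in 1 of its libraries and an interval that excluded no change. For both lines together they were up to 10 genes per direction at least 1.5-fold different in both lines with at least 5 CPM in each, ranked by the smaller fold. For the line contrast they were the 10 largest folds per direction among genes past the test with at least 5 CPM in both libraries of the higher line, and for the difference of responses the 5 largest per direction. Some genes this rule picked are not reported here. Sex-linked marker genes and genes with no symbol were left out, and from each list up to 4 members with the largest folds and at least 5 CPM in 1 library were named. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

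Alternatives were median-ratio size factors, total counts, a prior count of 0.5, other expression filters, the DESeq2 1.42.0 Wald test, models without the blocking term, leaving out each library or line, and random lists not matched on expression. Thinning all libraries to the smallest total, removing trends of GC content and length, and exchanging the coating labels in HepG2 were added after seeing the data. The GC and length trend was taken as the median in each of 10 by 10 bins, either of the folds or of each library's levels; the version on single libraries was added after the result on folds was known. GC content was at hand for 98.6% of the genes compared between lines.

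The tests were tried on simulated data made from the real means and library sizes with 200 changed genes. Every simulated gene had the same biological coefficient of variation, 0.138, and no change differed between lines or plates. Real genes vary in both, so the rates called may be too favourable. For the coating contrast over 15030 simulated genes, 78.6% of 98 genes changed 2-fold and 90.5% of 95 genes changed 4-fold were called, and 5 unchanged genes were called. For the line contrast over 14940 genes, 76.0% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold were called, with 8 unchanged genes called. The binomial interval was tried apart from these, on a Huh7 pair simulated by Poisson counting alone with no biological variation. It covered the simulated ratio for 95.6% of 14964 genes. This checks counting error only and says nothing of the spread between real libraries. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.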

Results

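Huh7 and HepG2 liver cancer cells were compared after 2 days on uncoated plates and on plates coated with rat tail collagen 1, with 1 library for each combination. Between 20752 and 21374 genes had a count above 0 in each library. In Huh7, 13651 genes were measured and 83.7% of them lay within 1.5-fold between the plates; in HepG2 these were 13691 genes and 85.7%.

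On collagen, some genes of adhesion, matrix remodelling and the cytoskeleton rose over both lines, and most genes of hepatocyte plasma proteins and sterol synthesis fell. The genes that led the rise included AXL, a receptor tyrosine kinase, LOXL2, a lysyl oxidase that crosslinks collagen, TNS4, which binds integrin tails, and FLNC, a filamin. The fall was led by genes that hepatocytes express, such as FABP1, which encodes the liver fatty acid binding protein, and SERPINC1, which encodes antithrombin. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, blocked by line, 458 genes rose and 265 fell of 15209 tested, and 709 of these 723 had the same direction in both lines. This share is largely set by the test, whose residual is the difference between the lines. Of these genes, 261 rose and 80 fell at least 2-fold, and 80 rose and 6 fell at least 4-fold.

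AXL went from 1.08 to 20.5 CPM in Huh7 and from 6.82 to 52.7 CPM in HepG2, a log2 fold of 3.49 (SE 0.25) over both lines. KRTAP3-1, a keratin-associated protein gene, rose by 3.30 (SE 0.30) and LOXL2 by 3.23 (SE 0.36). MYOF, a ferlin of membrane repair, rose by 2.86 (SE 0.27), TNS4 by 2.71 (SE 0.22), SOCS2, an inhibitor of cytokine signalling, by 2.67 (SE 0.36), and GPRC5A, an orphan receptor, by 2.64. PFKP, which encodes a phosphofructokinase, and FLNC rose by 2.35 (SE 0.21) and by 2.25. RGPD5 had the largest fold, 4.86 (SE 0.38), but it has near-identical paralogs and its level is uncertain. Adjusted p by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment was 9.3e-09 for AXL, 2.3e-08 for TNS4 and 2.9e-05 for SOCS2.

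Among genes lower in both lines, GSTA1, a glutathione transferase, was at -1.80 (SE 0.20), SERPINC1 at -1.59 (SE 0.17) and FABP1 at -1.55 (SE 0.16). SLC30A10, a manganese transporter, was at -1.43 and BHMT, an enzyme of methionine synthesis, at -1.27 (SE 0.26). SERPINA6, which encodes the cortisol binding protein, was at -1.26 (SE 0.16), MT1F, a metallothionein, at -1.22 (SE 0.16), and PRODH2, an enzyme of hydroxyproline breakdown, at -1.21 (SE 0.17). All of these fell by the test; GSTA1 and MT1F have close paralogs and are uncertain. AC005943.1 was at -2.37, but it overlaps MBD3 and UQCR11 on the same strand and its level is uncertain.

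Lists of adhesion and cytoskeleton genes held genes that rose on collagen. Of 16 receptor genes for matrix, 4 rose, among them the integrin genes ITGA3 (2.76, SE 0.41), ITGA5 (1.39, SE 0.19) and ITGA2 (0.81, SE 0.19; 0.25 in Huh7 and 1.299 in HepG2), and 9 rose adjusted over the list alone. Of 23 focal adhesion genes 5 rose, with TGFB1I1 at 2.21 (SE 0.34), FHL2 at 1.29 (SE 0.21) and FLNA at 0.97 (SE 0.18), and 10 adjusted over the list alone. Of 19 cytoskeletal targets of SRF 5 rose, led by CNN1 (2.28, SE 0.29), a calponin, and TAGLN2 (1.13, SE 0.16), and 9 adjusted over the list alone. Targets of YAP rose in 5 of 19 cases by either count, with ANKRD1 at 2.05 (SE 0.17) and CCN1 at 1.34 (SE 0.17). Immediate early genes rose in 6 of 22 cases, among them FOSL1 (1.24, SE 0.19) and FOSL2 (0.94, SE 0.18), and 14 adjusted over the list alone.

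Of 25 matrix remodelling genes 10 rose and 1 fell, and 11 and 1 adjusted over the list alone; besides LOXL2 these included the metalloproteinase MMP24 (1.99, SE 0.26), the metalloproteinase inhibitor TIMP1 (1.49) and the transglutaminase TGM2 (1.35, SE 0.16). Of 25 structural matrix genes 5 rose, with COL1A1 at 3.44 (SE 0.56), COL4A1 at 2.71 (SE 0.45) and NID2 at 1.63 (SE 0.30), and 7 rose and 1 fell adjusted over the list alone. Of 17 genes of the TGF-beta pathway 7 rose and 9 adjusted over the list alone, among them TGFB2 (2.43, SE 0.55) and CDKN2B (1.90, SE 0.23). The folds of COL1A1 (4.88 in Huh7 and 1.13 in HepG2), COL4A1 (2.72 and 0.39), TGFB2 (2.44 and 0.39) and CDH2 (2.56 and 0.45) rest mostly on Huh7, with COL4A1 and TGFB2 each at 1 and 2 counts in HepG2. NID2 was at only 0.05 and 0.37 CPM in HepG2, so its fold also rests mostly on Huh7. Epithelial genes rose in 6 of 17 cases and 11 adjusted over the list alone, with KRT19 at 2.04, KRT18 at 1.11 (SE 0.18) and CLDN6 at 1.10 (SE 0.20). Mesenchymal genes rose in 4 of 9 cases by either count, with CDH2, VIM, TAGLN (1.27, SE 0.17) and S100A4 (0.98, SE 0.18). VIM was higher in Huh7 alone, from 5.12 to 32.8 CPM, and was at 0.752 and 0.743 CPM in HepG2. VIM and CDH2 did not pass in DESeq2 or with GC and length trends removed, and COL1A1 did not pass with these removed.

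Genes of plasma proteins fell together. Of 21 such genes 13 fell, and 18 adjusted over the list alone, with APOC3, an apolipoprotein, at -1.38 (SE 0.21) and APOH at -1.34 (SE 0.18). Of 16 acute phase genes 7 fell, with HP (haptoglobin) at -0.95 (SE 0.17), SAA4 at -0.84 (SE 0.19) and ORM1, uncertain beside its paralog ORM2, at -0.73 (SE 0.16); adjusted over the list alone 1 rose and 10 fell. Sterol synthesis genes fell in 18 of 25 cases and 23 adjusted over the list alone, including HMGCS1 (-1.21, SE 0.16), ACAT2 (-0.94, SE 0.16) and CYP51A1 (-0.91, SE 0.16). Of 18 lipogenesis genes 8 fell, with GPAM at -0.82 (SE 0.16) and FADS1 at -0.72 (SE 0.16); adjusted over the list alone 1 rose and 9 fell. Of 15 genes of sugar and amino acid metabolism 4 fell and 6 adjusted over the list alone, led by AGXT (-1.32, SE 0.19).

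Of 18 genes of drug metabolism 5 fell and 6 adjusted over the list alone, with GSTA2, a close paralog of GSTA1 and uncertain, at -1.38 (SE 0.34; -0.34 in Huh7, where the interval of -0.88 to 0.15 included no change, and -2.20 in HepG2), SULT2A1 at -1.17 and ADH4 at -1.09 (SE 0.18). Of 18 genes of oxidative stress and metal response 7 fell and 8 adjusted over the list alone, with the metallothioneins MT1M (-1.34, SE 0.25) and MT1G (-1.30, SE 0.17), uncertain as paralogs, and the aldo-keto reductase AKR1B10 (-0.97, SE 0.16). Hepatocyte transcription factor genes fell in 1 of 19 cases by either count, NR1H4 at -1.06 (SE 0.16). Fetal and progenitor genes went both ways, 2 up and 3 down of 15, or 2 and 4 adjusted over the list alone, with SOX4 at 1.29 (SE 0.18) and AFP at -0.94 (SE 0.21). Fatty acid oxidation genes were 1 up and 2 down of 15, or 1 and 5 adjusted over the list alone, with ANGPTL4 at 1.14 (SE 0.33). ACOT1, uncertain beside its paralog ACOT2, was at -0.73 (SE 0.17). Wnt targets were 1 up and 2 down of 16, or 5 and 3 adjusted over the list alone, with AXIN2 at 0.59 (SE 0.16) and RHBG at -0.90 (SE 0.16).

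Hypoxia and glycolysis genes rose in 3 of 25 cases, SLC2A3 at 2.13 (SE 0.21) and SLC2A1 at 0.95 (SE 0.18) among them, and 5 adjusted over the list alone. Inflammatory genes were 3 up and 1 down of 16 by either count, IL11 at 1.75 (SE 0.31), LIF at 1.26 (SE 0.21) and CCL20 at -1.20 (SE 0.20). Growth factor genes were 2 up and 1 down of 18, or 6 and 1 adjusted over the list alone, with EREG at 1.87 (SE 0.36) and FGFR2 at -1.16 (SE 0.31). In Huh7, EREG was at 0.13 and 0.28 CPM and IL11 at 0.16 and 0.62 CPM, so both rest mostly on HepG2. Interferon genes rose in 1 of 16 cases by either count, IRF9 at 0.93 (SE 0.21). Among markers of other cell types, 1 of 4 stellate cell genes and 3 of 6 endothelial genes rose by either count, the latter ESAM (2.77, SE 0.24), TIE1 (2.69, SE 0.50) and LYVE1 (1.27, SE 0.27). TIE1 was at 2 counts and LYVE1 at 7 counts in each Huh7 library, so both rest on HepG2.

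By the edgeR quasi-likelihood test 0 genes passed in 9 lists, and DESeq2 called 0 in each. These were S phase genes (19 tested, 0 up and 1 down at an unadjusted p under 0.05), G2 and M phase genes (20, 0 and 3), p53 targets (18, 2 and 0), genes of the unfolded protein response (22, 1 and 1), heat shock genes (12, 3 and 0), leukocyte markers (5, 1 and 1), mitochondrially encoded genes (13, 0 and 1) and ribosomal protein genes (28, 0 and 0). The last of the 9 was nuclear noncoding RNAs (6, 1 and 1). Adjusted over the list alone 2 heat shock genes rose, 1 leukocyte marker rose and 1 fell, and 1 mitochondrially encoded gene fell.

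DESeq2 called 214 genes higher and 139 lower, 348 of them among the 723, and lost 22 of the list members named for collagen, VIM, CDH2, COL4A1, TGFB2 and TIE1 among them. It called 2 of the 17 TGF-beta genes, 3 immediate early, 2 mesenchymal, 3 receptor, 4 focal adhesion, 4 SRF target, 5 YAP target, 3 structural matrix and 5 epithelial genes higher, and 8 remodelling genes higher and 1 lower. It called 2 hypoxia genes, 1 endothelial and 1 stellate cell marker higher, 2 inflammatory genes higher and 1 lower, 1 Wnt target each way, 1 fetal gene higher and 3 lower, and 0 interferon and 0 growth factor genes. Lower in DESeq2 were 12 plasma protein, 7 acute phase, 15 sterol synthesis, 5 lipogenesis, 3 sugar and amino acid, 3 drug metabolism, 5 oxidative stress and metal, 1 fatty acid oxidation and 1 transcription factor genes. In Huh7 the fold followed transcript GC content (rho 0.447, against -0.109 in HepG2), and with GC and length trends removed, an alternative added after seeing the data, 318 genes rose and 187 fell.

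**Figure D1:**
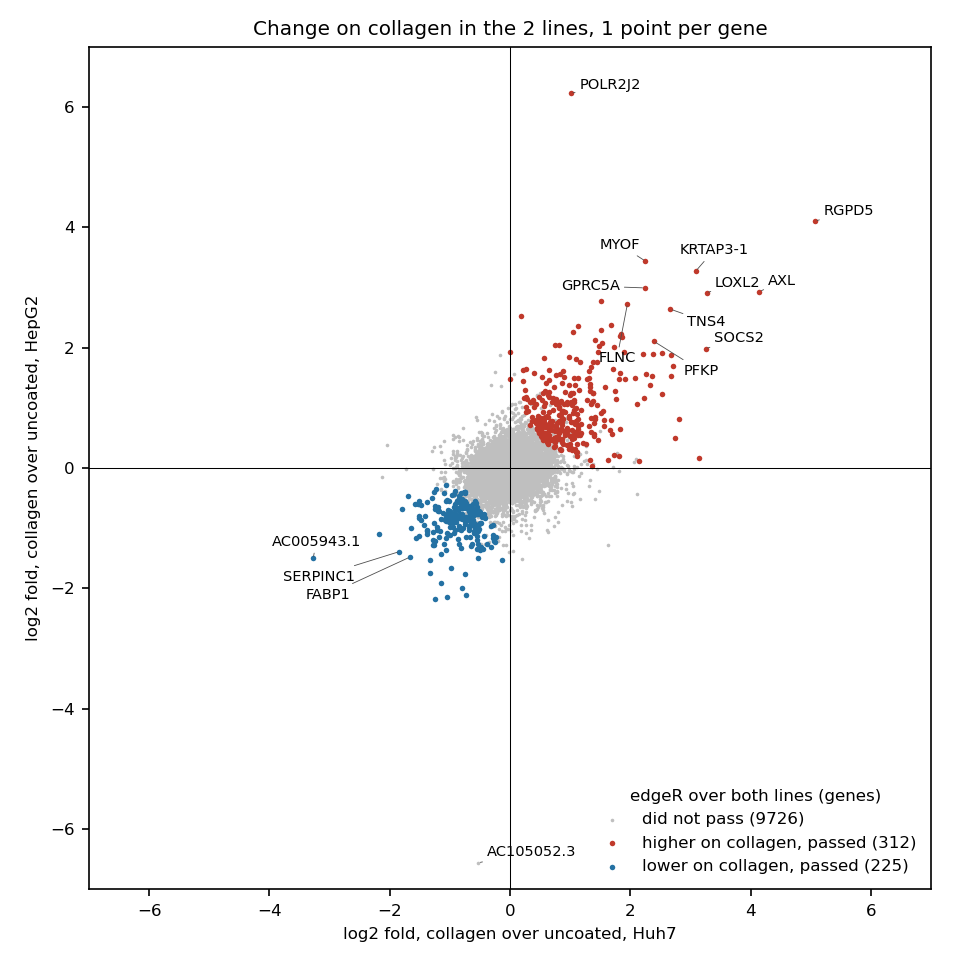
Log2 folds on collagen in Huh7 and HepG2 for 10263 genes, of which 312 rose and 225 fell by the edgeR quasi-likelihood test over both lines.

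**Figure D2:**
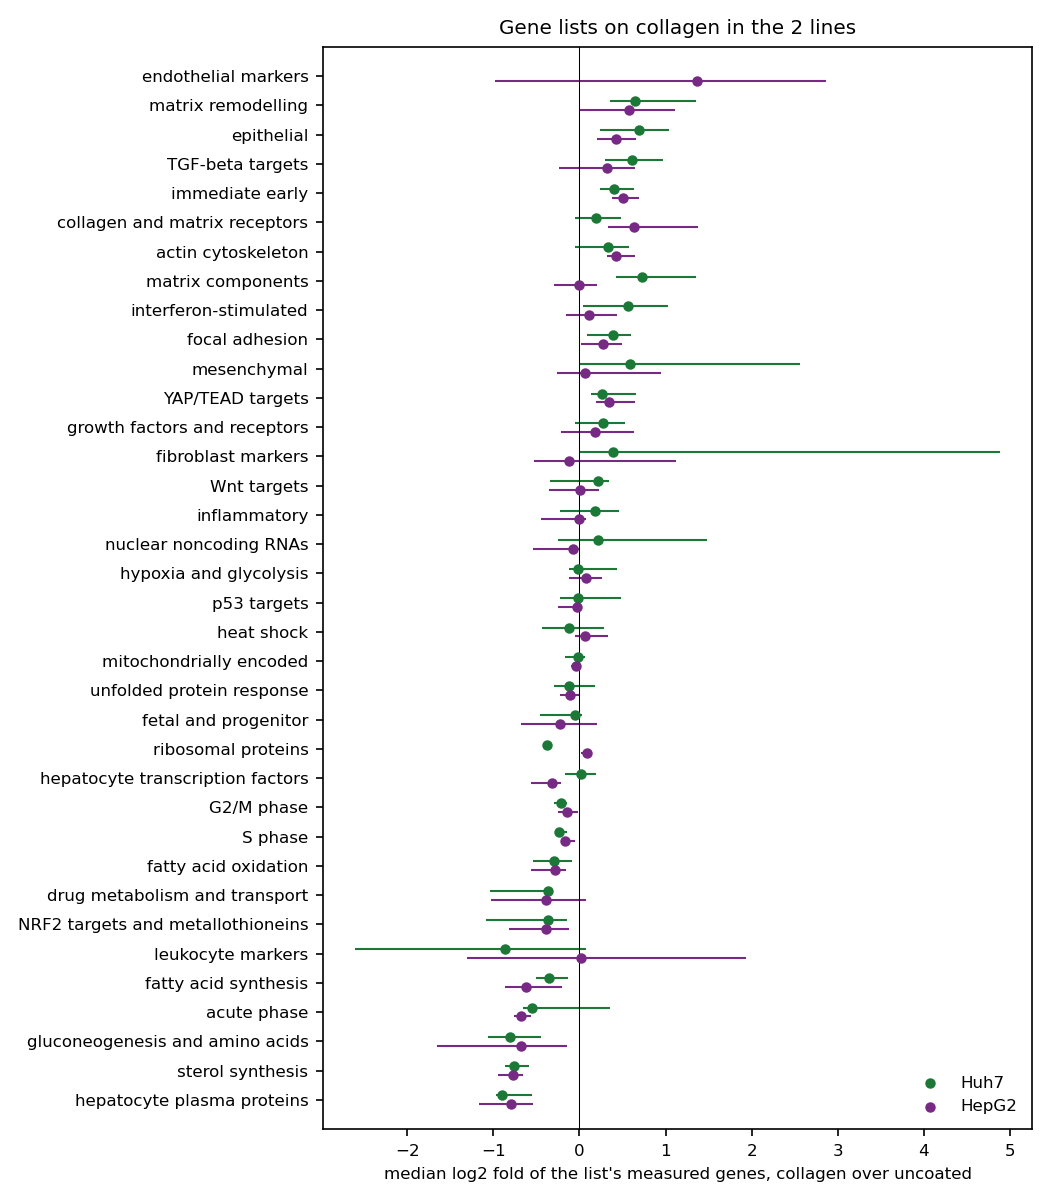
Median log2 fold on collagen of each gene list in Huh7 and in HepG2; plasma protein genes were at -0.89 and -0.79.

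Within Huh7, matrix, natriuretic peptide and annexin genes were among the highest on collagen relative to uncoated plates, and a urea cycle gene and a chemokine were among the lowest. At least 2-fold, 502 genes were higher and 277 lower, beside a mean of 10.2 in simulated pairs that differed by counting alone. Under total counts, where the log2 folds shifted by a median of 0.122, 622 genes were higher and 199 lower. COL1A1 was at 17 and 396 counts, a log2 fold of 4.88 (interval 4.39 to 5.88), AXL at 4.15 (3.74 to 4.81) and NPPB, which encodes a natriuretic peptide, at 3.89. ANXA1, an annexin, was at 3.54 (2.99 to 4.59), LOXL2 at 3.27, SOCS2 at 3.25, UNC13D, a gene of granule release, at 3.15, KRTAP3-1 at 3.09 and SLC7A7, an amino acid transporter, at 3.04 (2.75 to 3.42). Lower on collagen were the metallothionein MT1H, uncertain as a paralog, at -2.18 (-2.63 to -1.82), CPS1, the first enzyme of the urea cycle, at -2.12 with 212 and 32 counts, SERPINC1 at -1.84 (-1.99 to -1.71), the chemokine gene CCL20 at -1.79 and FRZB, a Wnt antagonist, at -1.78. RGPD5 at 5.07, HSPE1-MOB4 at -2.04, TGIF2-RAB5IF at -1.98, PALM2AKAP2 at -1.73, AC005943.1 at -3.27 and AC010422.3 at -2.01 share sequence with other genes and are uncertain.

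Among the lists in Huh7, structural matrix genes had a median of 0.73, epithelial genes 0.69, matrix remodelling genes 0.64 and TGF-beta genes 0.61, each above all or nearly all of 10000 matched random lists (percentile 100). Plasma protein genes were at -0.89, genes of sugar and amino acid metabolism at -0.81 and sterol synthesis genes at -0.76, each at percentile 0. Interferon genes were at 0.56 (percentile 99.9) and ribosomal protein genes at -0.38 (percentile 0.04). Only 10 interferon genes were measured in Huh7, and most genes of this list were higher in HepG2. Matching used the mean over all 4 libraries, so their random lists may hold genes better expressed in Huh7. The interferon percentile is therefore uncertain. S phase genes were at -0.24 (percentile 3.91), with 17 of 19 below 0, and G2 and M phase genes at -0.21 (percentile 5.8), with 19 of 20 below 0. Their matched random lists also lay below 0, at medians of -0.11 and -0.10. This comparison is between 2 libraries, not conditions, with no replicate check and no test.

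Within HepG2, a neuregulin, a ferlin and a cathepsin gene were among the highest on collagen relative to uncoated plates, and glutathione transferases and a glycerol channel among the lowest. At least 2-fold, 448 genes were higher and 308 lower, beside a mean of 17.6 from counting alone. NRG1, which encodes a ligand of ERBB receptors, was at 2 and 261 counts, a ratio of 121 (33.1 to 1003). MYOF was at a log2 fold of 3.44, KRTAP3-1 at 3.28, MYEOV at 3.23 (2.72 to 3.97), the cathepsin gene CTSE at 3.20, AXL at 2.93 and LOXL2 at 2.91. Lower were AQP9, an aquaglyceroporin, at -2.26 (-3.01 to -1.72), GSTA2 at -2.20 (-2.54 to -1.91), GSTA1 at -2.18 (-2.29 to -2.08), both uncertain as paralogs, COL2A1 at -2.11, LIPG, an endothelial lipase, at -2.07 and ADAM11 at -2.04. ACSM2B at -2.15 and ACSM2A at -2.04 are paralogs, RGPD5 was at 4.11, and AL645922.1 at -2.01 overlaps C2 and CFB, so all 4 are uncertain. POLR2J2 was at 0 and 137 counts, at least 42.3-fold higher, and AC105052.3 at 160 and 0 counts, at least 57.6-fold lower; the genes overlap on the same strand, and both levels are uncertain.

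Among the lists in HepG2, receptors for matrix had a median of 0.63, matrix remodelling genes 0.57, immediate early genes 0.51, epithelial genes 0.42 and SRF targets 0.42, all at percentile 100. Plasma protein genes were at -0.79, sterol synthesis genes at -0.77, acute phase genes at -0.68, genes of sugar and amino acid metabolism at -0.67 and lipogenesis genes at -0.62, all at percentile 0. Hepatocyte transcription factor genes were at -0.32 (percentile 0), with 17 of 19 below 0, where they were at 0.02 in Huh7, and genes of oxidative stress and metal response at -0.39 (percentile 0). Ribosomal protein genes were at 0.08 (percentile 97.3), with 24 of 28 above 0. Structural matrix genes were at -0.01 (percentile 51.7) and mesenchymal genes at 0.07 (percentile 68.4). S phase genes were at -0.17 (percentile 0.38) and G2 and M phase genes at -0.15 (percentile 0.78), with 15 of 19 and 14 of 20 below 0.

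The coating folds of the lines went together across genes. Over 10413 genes Pearson's r was 0.463 (0.431 to 0.497) and Spearman's rho 0.279 (0.258 to 0.298). At least 1.5-fold, 202 genes were higher in both lines where independent lists would share 22.2, 170 were lower in both where they would share 20.1, and 12 went opposite ways where 42.4 would; at 1 CPM these were 68 and 109. At least 2-fold, over the 12715 genes at 1 CPM, 138 genes were higher in both lines (9.06 by independent lists) and 55 lower in both (3.37). Genes are not independent replicates, so no p is given.

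For some genes the coating folds of the lines lay far apart. The log2 fold in Huh7 minus that in HepG2 was 2.99 for UNC13D and 2.26 for NPDC1, and -2.34 for MECOM, a transcription factor gene. CPS1 was at -1.98, AC105052.3 at 6.03 and POLR2J2 at -5.22, the last 2 uncertain. These differences were not tested, because they leave no residual degrees of freedom.

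Most p53 targets, interferon genes and acute phase genes were higher in HepG2 than in Huh7, and most sterol synthesis and cell cycle genes were lower. HepG2 carries normal p53 and Huh7 a mutant p53, as is known of these lines. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, blocked by coating, 3557 genes were higher in HepG2 and 3406 lower of 15209 tested. With 1 library left out and no coating term these were 1237 to 1706 and 942 to 1561. Of 18 p53 targets 17 were higher in HepG2 and 0 lower by either count, among them CDKN1A, the cell cycle inhibitor p21 (8.71, SE 0.26), at 0.391 and 0.855 CPM in Huh7 and 216 and 278 CPM in HepG2, and FDXR (4.07, SE 0.20).

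The 10 largest folds towards HepG2 included genes at 0 counts in Huh7, whose lower bounds do not rank them. Among these were the collagen genes COL4A5 (at least 790-fold) and COL4A6 (at least 292-fold), CADPS2 (at least 503-fold), FAS, a death receptor (at least 388-fold), EDA2R (at least 286-fold), PTCHD4 (at least 242-fold), CCDC144NL-AS1 (at least 239-fold) and PSMB9 (at least 238-fold). ACTA2, also among the 10, was at 1 count in Huh7 and 2762 in HepG2, a ratio of 3445. Genes at 0 counts in HepG2 among the 10 largest folds towards Huh7 were MAGEA12 (at least 851-fold, uncertain beside other MAGEA genes), HDHD5 (at least 407-fold), LINC02381 (at least 397-fold), CTSF (at least 282-fold), LINC01419 (at least 277-fold), RPL39L (at least 220-fold), PGAP4 (at least 209-fold), GTSF1 (at least 180-fold) and ZNF302 (at least 169-fold). GSTP1, also among those 10, was at 7 counts in HepG2 and 36597 in Huh7, a ratio of 4192. Of 10509 genes at 5 CPM or more in both HepG2 libraries 12 had 0 counts in Huh7, and of 10395 such genes in Huh7 19 had 0 counts in HepG2.

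Interferon genes were higher in HepG2 in 13 of 16 cases and lower in 0, or 14 and 0 adjusted over the list alone, with BST2 at 6.92 (SE 0.25). Inflammatory genes were 13 and 1 of 16 by all genes, with IL11 at 5.32 and LCN2 at 5.23, and acute phase genes 13 and 1 of 16 by either count, with ITIH3 at 6.27 (SE 0.21) and SAA4 at 5.65 (SE 0.21). Plasma protein genes were 11 and 6 of 21, or 13 and 6 adjusted over the list alone, with PLG at 6.81 (SE 0.27) and GC at -3.88 (SE 0.47). Genes of oxidative stress and metal response were 13 and 2 of 18, with AKR1B10 at 3.02 and MT1M, uncertain, at -2.84. Drug metabolism genes were 10 and 3 of 18, or 12 and 4 adjusted over the list alone, with GSTA1, uncertain, at 3.95 (SE 0.22). Hypoxia genes were 12 and 4 of 25, with NDRG1 at 1.94 and CA12 at -4.15.

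Higher in Huh7 were sterol synthesis genes, 2 higher in HepG2 and 13 lower of 25, or 2 and 15 adjusted over the list alone, INSIG1 among them at a ratio of 680 with 2 counts in HepG2. Lipogenesis genes were 3 and 8 of 18, with FADS2 at -3.70, S phase genes 1 and 11 of 19, with RFC4 at -1.18, and G2 and M phase genes 1 and 11 of 20, with UBE2C at -2.20 (SE 0.17). Hepatocyte transcription factor genes were 2 and 8 of 19 by either count, though NR0B2 was at 5.23 (SE 0.20). The median log2 fold of this list was -0.04 (percentile 45.4), with 9 genes above 0 and 10 below, so the list as a whole was not shifted. Growth factor genes were 6 and 10 of 18, with PDGFA at -4.34 and FGFR2 at -4.21, and TGF-beta genes 3 and 7 of 17, with SMAD6 at -3.18.

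Most other lists were mixed, though receptors for matrix, immediate early genes and genes of sugar and amino acid metabolism leaned towards HepG2. Mesenchymal genes were 4 and 4 of 9, with ACTA2 at 11.45 (SE 0.39) and VIM at -4.32 (SE 0.42), PDGFRB at -3.81 (SE 0.23) and CDH2 at -3.52 (SE 0.46). Where no second count is given, the count adjusted over the list alone was the same. Receptors for matrix were 7 and 2 of 16 (8 and 2 adjusted over the list alone), focal adhesion genes 7 and 5 of 23 (7 and 6), structural matrix genes 7 and 5 of 25 with SPARC at 7.28 (SE 0.34), and remodelling genes 7 and 8 of 25 (8 and 8) with MMP14 at -4.63 (SE 0.22). Epithelial genes were 7 and 7 of 17 (7 and 8), with CLDN6 at 8.18 and CDH1 at -2.24 (SE 0.20), YAP targets 5 and 7 of 19, SRF targets 3 and 5 of 19, and Wnt targets 7 and 7 of 16 with DKK1 at -3.79 (SE 0.19). Fetal and progenitor genes were 5 and 5 of 15 (6 and 5), with GPC3 at 3.30 (SE 0.18) and SALL4 at -5.42. Fatty acid oxidation genes were 5 and 5 of 15 (6 and 5) with CPT1A at 2.03, and genes of sugar and amino acid metabolism 7 and 3 of 15 (7 and 4) with GLS2 at 4.93. Immediate early genes were 8 and 3 of 22 with FOSL1 at 2.69, genes of the unfolded protein response 3 and 6 of 22 (2 and 5), and heat shock genes 2 and 2 of 12 with HSPA1A, uncertain beside its near-identical copy HSPA1B, at 3.37 (SE 0.17).

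Endothelial markers were higher in HepG2 in 5 of 6 cases and lower in 0, or 5 and 1 adjusted over the list alone, with LYVE1 at 6.49 and ESAM at 4.27, stellate cell markers 1 and 2 of 4 and leukocyte markers 3 and 1 of 5. Ribosomal protein genes were 0 and 6 of 28 (0 and 5 adjusted over the list alone) with RPL8 at -0.71, and nuclear noncoding RNAs 3 and 1 of 6 with NEAT1 at 0.95 and MALAT1 at 0.68. Of 13 mitochondrially encoded genes the edgeR quasi-likelihood test called 0, with 0 and 1 at an unadjusted p under 0.05 and 0 and 2 by DESeq2. DESeq2 called 2262 genes higher in HepG2 and 2096 lower.

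By list, DESeq2 called 16 p53 targets higher in HepG2 and 0 lower, 10 and 0 interferon, 10 and 1 inflammatory, 12 and 1 acute phase, 13 and 5 plasma protein, 10 and 1 oxidative stress and metal, 7 and 1 drug metabolism and 8 and 4 hypoxia genes. It called 1 and 11 sterol synthesis, 1 and 6 lipogenesis, 1 and 10 S phase, 1 and 10 G2 and M phase, 1 and 6 hepatocyte transcription factor, 5 and 9 growth factor and 3 and 7 TGF-beta genes. Of the other lists these were 4 and 4 mesenchymal, 7 and 2 receptor, 4 and 4 focal adhesion, 7 and 4 structural matrix, 5 and 6 remodelling, 7 and 6 epithelial, 4 and 6 YAP target, 2 and 5 SRF target and 7 and 5 Wnt target genes. They were 5 and 4 fetal, 5 and 4 fatty acid oxidation, 5 and 2 sugar and amino acid, 8 and 2 immediate early, 1 and 5 unfolded protein response and 2 and 2 heat shock genes, and 5 and 0 endothelial, 1 and 1 stellate cell and 2 and 1 leukocyte markers. Ribosomal protein genes were 0 and 8 and nuclear noncoding RNAs 3 and 0.

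**Figure D3:**
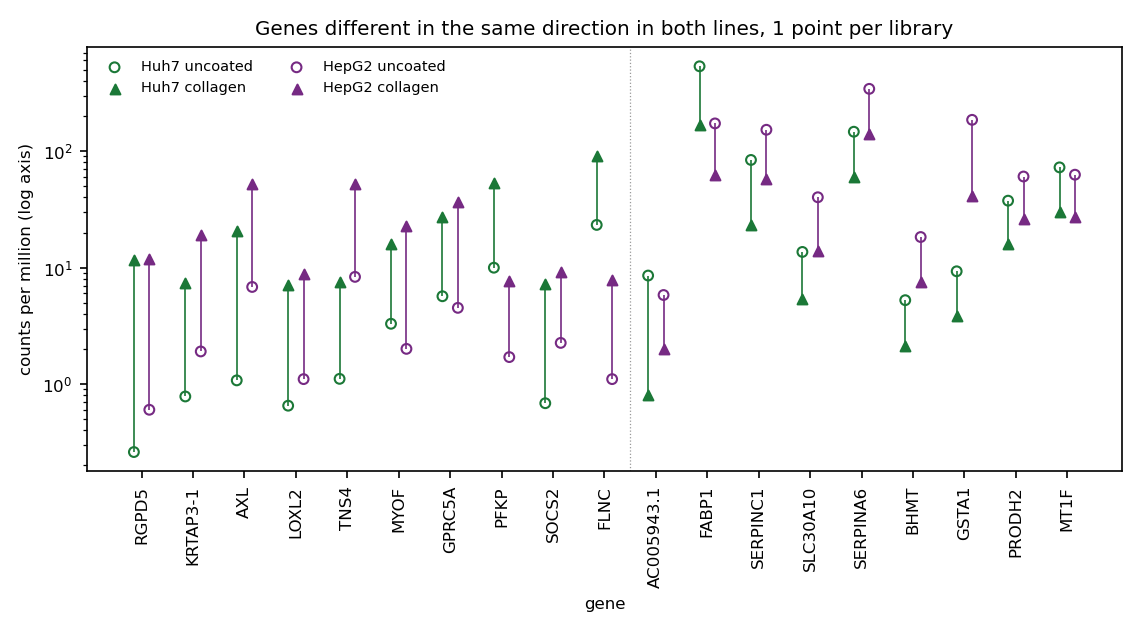
CPM of named genes in each of the 4 libraries; AXL was at 1.08 and 20.5 CPM in Huh7 and 6.82 and 52.7 CPM in HepG2.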

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

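No test was run on the differences in this part, and none was chosen after the result was seen. Among genes named for their difference of response, 4 had folds on collagen of opposite sign in the 2 lines, each with a counting interval that excluded no change in both under TMM and median-ratio scaling. Under total counts the interval of COTL1 in Huh7 (-0.13 to 0.03) and that of GPRC5B in HepG2 (-0.81 to 0.01) included no change. BMF, a pro-apoptotic member of the BCL2 family, was higher on collagen in Huh7 at a log2 fold of 1.63 and lower in HepG2 at -1.27, a difference of 2.90. GPRC5B, an orphan G protein-coupled receptor, was at 2.11 in Huh7 and -0.43 in HepG2, a difference of 2.54. HSPE1-MOB4, a readthrough gene whose reads are shared with HSPE1 and MOB4 and whose level is uncertain, was at -2.04 in Huh7 and 0.39 in HepG2, a difference of -2.43. COTL1, which encodes an actin-binding protein, was at -0.17 in Huh7 and 1.88 in HepG2, a difference of -2.06. The difference between the lines was not tested, because 1 library per group leaves no degrees of freedom for it.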

How the results depend on the processing

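Thinning to equal depth, the removal of GC and length trends and the exchange of coating labels in HepG2 were chosen only after the result was seen; the other alternatives were planned. With a filter of 5 CPM in place of 1 CPM, 247 genes were at least 2-fold higher and 130 lower on collagen in Huh7, and 239 and 140 in HepG2; with no filter they were 818 and 422 in Huh7, and 464 were lower in HepG2, by construction from fewer or more genes. DESeq2 called 214 genes higher and 139 lower on collagen over both lines, and 2262 higher and 2096 lower in HepG2 than in Huh7; the cause was not tested. Without the line term 0 genes were higher and 0 lower by the edgeR quasi-likelihood test (159 at an unadjusted p under 0.05), since the difference between lines then counts as spread. With coating labels exchanged in HepG2 the same test called 0 genes, and 151 at an unadjusted p under 0.05. A change shared by both lines then counts as spread. The biological coefficient of variation was 0.244 and the prior degrees of freedom 3.28, against 0.138 and 22.7. The exchange is therefore no measure of false calls. Leaving out 1 library, which also took out the coating term, left 1237 to 1706 genes higher in HepG2 and 942 to 1561 lower; taking out the term alone left 2463 and 2348. Over the same libraries left out in turn, the log2 fold of HepG2 over Huh7 ranged from -0.64 (without collagen HepG2) to 4.82 (without collagen Huh7) for AXL and from -3.575 (without uncoated Huh7) to 1.53 (without collagen Huh7) for COL1A1, against 1.84 and -1.78 with all libraries. With no coating term the fold between lines takes in the coating fold of these genes. Leaving out a line gives a value with no test: VIM was at -0.016 in HepG2 alone, and of list members that had not passed 10 changed sign without Huh7 and 5 without HepG2. Pearson's r between lines was 0.409 at 1 CPM, 0.528 with GC and length trends removed from each library and 0.535 with them removed from the folds; Spearman's rho was 0.254 at 20 CPM, and 0.372 and 0.377 after the same removals. Genes at least 1.5-fold higher in both lines numbered 368 at 1 CPM and 107 at 20 CPM, and 107 were lower at 20 CPM, as the number of genes changed; 68 went opposite ways at 1 CPM, where independent lists would give 109. Under total counts the Huh7 library pair had 622 genes higher and 199 lower, 75.8% higher against 64.4% under TMM. All 20 genes picked for both lines kept direction under every alternative, which their choice by a same-direction fold in both lines largely fixed. All 20 lost their call without the line term, and BHMT alone in DESeq2. Of 131 list members named for collagen, 22 lost their call in DESeq2, 15 with GC and length removed, and without the line term all 77 that had passed lost it. Of 134 named for the lines, 29 to 45 lost theirs with 1 library left out, 14 without the coating term, 4 in DESeq2 and 1 with GC and length removed. Of the 142 list medians 15 moved beyond their interval under total counts, 3 under median-ratio factors and 7 with GC and length removed, where 5 percentiles became stronger and 2 weaker. With 1 library per group, depth limits a fold within a line only through counting, and a level below 0.150 CPM could not be told from 0 in the shallowest library.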

Other observations

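The gene families in this part, and the tests on them, were chosen only after the values were seen. On collagen over both lines, by the edgeR quasi-likelihood test, 7 of 11 S100 genes rose, with S100A3 at 2.35 (SE 0.22), S100A11 at 1.83 and S100A6 at 1.60, and 4 of 10 annexin genes, with ANXA1 at 3.56 (SE 0.42) and ANXA3 at 2.06 (SE 0.17). Tubulin genes rose in 5 of 14 cases, with TUBA1A at 1.65 (SE 0.18) and TUBB2B at 1.54 (SE 0.19), keratin genes in 6 of 9, with KRT80 at 2.19 (SE 0.23), and both thymosin genes, TMSB4X at 1.46 (SE 0.18) and TMSB10 at 1.41. Tubulin and thymosin genes have close paralogs and are uncertain. LGALS1, a galectin, was at 2.26 (SE 0.19). DESeq2 called 6 S100, 4 annexin, 5 tubulin, 4 keratin and 2 thymosin genes. Of 4 UGT2B genes, which are close paralogs and uncertain, 2 fell, and 1 in DESeq2, with UGT2B4 at -1.30 (SE 0.17).

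These endothelial-type genes were also chosen after their values were seen. In HepG2, ESAM went from 12.8 to 71.7 CPM on collagen, TIE1 from 1.61 to 12.3 and ROBO4 from 0.953 to 5.34. CDH5 was at 2.56 and 1.53 CPM, VWF at 2.56 and 1.25, and KDR at 0 and 0.139.

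Of the tests on the agreement of the coating folds, depth and handling were chosen only after the result was seen, and the GC and length correction was an added alternative whose prediction was written before its result. After the median fold of each GC and length bin was removed, Pearson's r was 0.535 (0.504 to 0.565). Before the removal r was 0.463 (0.431 to 0.497), so it rose when these trends were taken away. The folds also followed GC content in opposite directions in the 2 lines. Both argue against these trends, as measured by the bins, as a source of the agreement. After thinning to equal depth Pearson's r was 0.461 (0.428 to 0.495). The HepG2 totals were already close, at 19957079 uncoated and 21038359 on collagen, so thinning changed mainly the uncoated Huh7 library. Thinning could therefore change r little whatever the cause, and that test could not decide on depth. The totals themselves argue against depth as the source of the agreement. In Huh7 they were lower on collagen, at 20419484 against 32349825 uncoated, while in HepG2 they were slightly higher. The design held 0 uncoated pairs handled apart, so a difference of handling shared by the coated plates may have moved both lines alike and could not be told from collagen. The folds followed GC content in Huh7 (rho 0.447) and hardly in HepG2 (-0.109), so a library difference within the Huh7 pair was not excluded, which bears on the Huh7 folds and on the differences between the lines.

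For the mesenchymal and collagen genes that were higher in the coated Huh7 library, the GC correction was added after seeing the data and the test for fibroblasts was planned. The median CPM of COL1A2, COL3A1, DCN and LUM over that of COL1A1 was 0.0101 (upper limit 0.0172), which counts against fibroblasts or stellate cells in that library. With GC and length trends removed from each library, COL1A1 went from 3.44 (SE 0.56) to 3.35 (SE 0.74), VIM from 2.08 (SE 0.39) to 2.18 (SE 0.51) and CDH2 from 2.09 (SE 0.44) to 2.23 (SE 0.50). By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment these were then at adjusted p 0.051, 0.063 and 0.055, and the calls ended because the SE grew and the prior degrees of freedom went from 22.7 to 7.35 while the folds stayed. COL4A1 kept its call, at 2.71 (SE 0.45) and 2.77 (SE 0.42).

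For the plasma protein genes, which were lower on collagen in both lines, the tests were planned, except that the GC and length correction was an alternative added after seeing the data. The least negative median over 3 scalings and both lines was -0.76, which counts against scaling. The highest upper bootstrap limit, over genes of the list, among these scalings and lines was -0.43, and it need not belong to that median. With the GC and length trend removed from the folds the less negative median was -0.79 (upper limit -0.52), which counts against that trend as the whole cause. A shared difference of handling was not separable here either, for the same reason of 0 uncoated pairs handled apart.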
